A study of Homo sapiens with 9 samples.

How the data were processed

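The cells were primary bronchial epithelial cells of human origin, kept for 14 days at an air-liquid interface. They were exposed to IL-13, to an antibody against EGFR or to both agents for the last 48 h of culture. Each of 9 arrays compared 1 treated sample with 1 of 3 independent control samples, so that every treatment group held 3 arrays. Per the labels, RNA was amplified with an Ambion MessageAmp kit, labelled through aminoallyl nucleotides and coupled to Cy3 or Cy5. The scanner software, the background correction, the normalization and the identity of the antibody are not given in the sources used here. Genome positions are not given either, so no build is named.

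The deposited values were read as log2 ratios of the Cy5 channel over the Cy3 channel of each array. The labels do not state the base of the logarithm. Base 10 would place ratios beyond the range of a scanner, while a natural logarithm was not excluded. With a natural logarithm every fold change given here would be too small, and directions and tests would stay as they are. All 9 arrays were centred close to 0 when deposited, which shows that the authors had normalized them in some way, and no value was missing. The files hold no channel intensities. Signal over background could therefore not be examined, and no filter on low signal was possible.

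The treated RNA carried Cy5 on 2 arrays and Cy3 on 1 array of the IL-13 group and of the anti-EGFR group, and Cy5 on 1 array and Cy3 on 2 arrays of the group with both. The arrays labelled opposite to the rest of their group were IL-13 replicate 3, anti-EGFR replicate 2 and replicate 2 of both treatments. Leaving out any of them leaves its group in 1 dye orientation, and the dye term then rests on the other groups. Values of the arrays with treated RNA in Cy3 were multiplied by -1 so that all values read treated over control. This reading was compared with the other one, in which the deposited values would already be turned. The median residual SD was 0.14 log2 units under the reading used and 0.18 under the other, and 71.5% of the features had the smaller residual under the reading used. The IL-13 response list served as an anchor of the overall sign, with 20 of its 22 measured members higher with IL-13, and is for that reason not independent evidence of the direction of the IL-13 effect.

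Probes were named through the supplied table of probe genes, in which 12995 probes had exactly 1 gene symbol and 10045 probes had none or several. Probes of the same gene were averaged, which concerned 423 genes. This gave 22431 features, of which 12386 were named genes and the rest single probes tested under their own identifiers. Probes of 1 gene were called in opposite directions for 45 genes with the antibody, for 54 genes with both treatments and for 29 genes in the comparison of both treatments with IL-13. EGFR, MUC5AC, MUC5B, SERPINB2 and AREG were not analysed here.

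Changes were tested with limma 3.58.1 in R 4.3.3. A linear model with 3 group coefficients and a probe-specific dye term was fitted to all 9 arrays, which left 5 residual degrees of freedom, and empirical Bayes moderation added 4.02 prior degrees of freedom. The 6 comparisons were each treatment against control, both treatments against each single treatment, and the interaction, which is the difference between the IL-13 effect with and without the antibody. Adjusted p values are Benjamini-Hochberg values over the 22431 features of a comparison, with a threshold of 0.05, and all tests are two-sided unless stated. The median standard error of a log2 change was 0.08 for a comparison with control, 0.12 between a pair of treatment groups and 0.15 for the interaction. The number of arrays limits this precision. The labels call the samples independent and do not say whether they came from separate donors or cultures, so the p values measure the spread between these samples.

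The titles of the arrays number the control, and arrays with the same number were taken to share 1 control sample. Deviations of arrays from their group means had a median correlation of 0.128 for the same number and of -0.0336 for different numbers. After the dye term the medians were 0.235 and -0.113, and single pairs ranged on both sides of 0.1. The pairing therefore comes from the labels. The control number entered no term of the model used, and a fit with it as a block was an alternative.

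Before the data were examined, 19 gene lists were fixed, and the samples, comparisons, alternatives and the rule for named genes were written down. The lists were IL-13 response, goblet and mucin, ciliated cell, basal cell, squamous, club and secretory, EGFR ligands and receptors, ERK output, cholesterol synthesis, cell cycle, interferon response, MHC class II, inflammatory mediators, ion transport, ER protein folding, NRF2 and xenobiotic, heat shock, mesenchymal, and leukocyte and endothelial. The last pair held markers of other cell types that a culture could contain. Lists were tested with cameraPR of limma at a preset inter-gene correlation of 0.01, with adjustment over the 19 lists of a comparison, and members were also counted with p values adjusted over the list alone. The alternatives for lists were camera with an estimated correlation and fry. The estimated correlation ended all 46 list calls, and its p is given beside each of them.

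The named genes of a comparison were the 12 largest rises and the 12 largest falls among genes that passed, with the same sign on all 3 arrays of the group where the comparison was against control. Where fewer than 5 genes passed, the 5 genes per direction with the smallest p were taken. The rule also named 16 genes in advance, passing or not, and up to 4 members of each list with the smallest p. For the interaction and for the genes shared between treatments, the 10 with the smallest p were taken.

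Alternatives covered the dye term, the control number as a fixed block or a random effect, centring and scaling of arrays, single probes, array weights, robust moderation, a fit of only the groups compared, other thresholds, the other reading of the direction, and the omission of each array in turn. An omission leaves 2 arrays in 1 group, and the spread is then pooled over all groups. The omission of all arrays of 1 control number was added after seeing the data.

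The model was tested on simulated data with the same 22431 features, of which 200 were changed. It recovered 99% to 100% of the 2-fold changes against control, 92% to 93% of those between treatment groups and 86% of those in the interaction. False calls numbered 6 to 21 per comparison, 3.02% to 9.55% of the calls. Their share was 9.55% for IL-13 against control and 8.46% for the interaction, above the threshold of 0.05. Of 380 list tests without an effect, 6.58% had an unadjusted p under 0.05, and a rise of 0.5 log2 units in the IL-13 response list was recovered in 20 of 20 runs. The simulated features were independent of each other and the arrays shared no controls. These runs therefore could not check the list test where genes are correlated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.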

Results

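The series measured gene expression in normal human bronchial epithelial cells grown at an air-liquid interface, where basal airway cells differentiate into ciliated and secretory cells. IL-13 is a type 2 cytokine, and EGFR is the receptor of epidermal growth factor. The study title names IL-13 and EGF receptor signaling, and the groups allow the effect of each agent to be compared alone and in the presence of the other. There were 3 arrays with IL-13, 3 with the anti-EGFR antibody and 3 with both, each set against a control sample. The SD of the log2 ratios over all probes was 0.21, 0.21 and 0.28 on the IL-13 arrays, between 0.43 and 0.50 on the antibody arrays, and between 0.42 and 0.52 on the arrays with both. Replicate 3 of the IL-13 group was labelled as IL-13 with a control antibody, whereas the other 2 were labelled as IL-13, and the labels do not say whether the remaining samples received a control antibody. In the text below, a value with ± is a log2 change with its standard error from limma, with n = 3 arrays per group, and fold changes assume base 2.

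**Figure D1:**
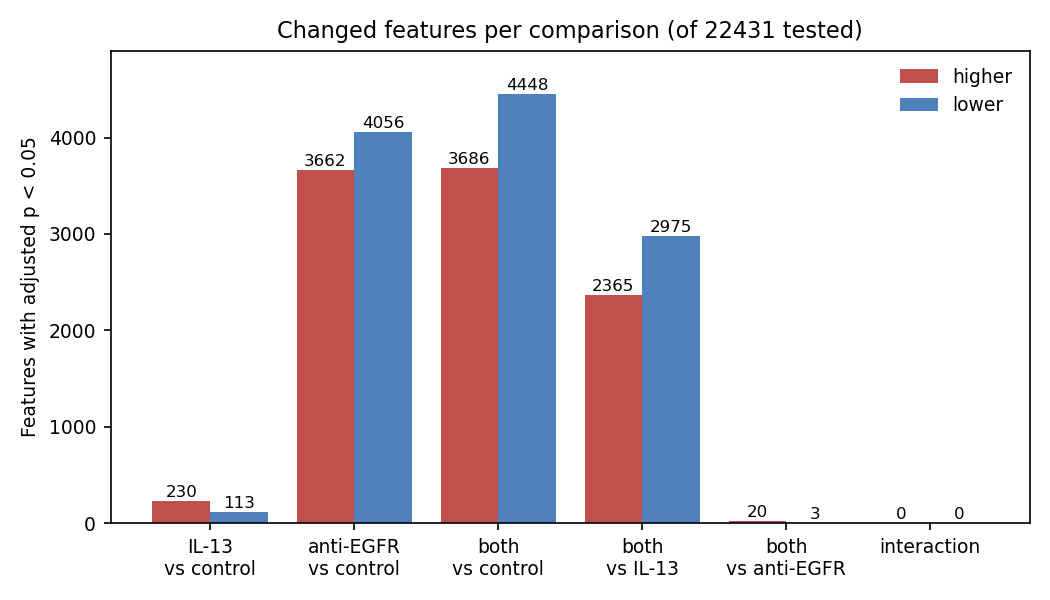
Number of features with an adjusted p under the threshold in each comparison, out of 22431 tested, split into higher (red) and lower (blue). The antibody comparisons held 7718, 8134 and 5340 features, IL-13 against control held 343, both against anti-EGFR held 23 and the interaction held 0.

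IL-13 alone raised several mucus-associated and type 2 genes. ITLN1, a lectin of goblet cells, rose by 3.45 ± 0.31 (adjusted p = 0.00104), CCL26, an eosinophil chemoattractant, by 3.44 ± 0.35 (adjusted p = 0.00201), and FCGBP, a mucus protein, by 3.24 ± 0.20 (adjusted p = 0.000354). FETUB rose by 3.28 ± 0.33, and ALOX15, a lipoxygenase, rose by 2.24 ± 0.16. TF, which encodes transferrin, fell by 1.91 ± 0.18 (adjusted p = 0.00148), and S100A8, a subunit of calprotectin, fell by 1.56 ± 0.23. In all, 230 features were higher and 113 lower, 1.53% of those tested, and 47 changed at least 2-fold. The balance of directions depended on the setting, with 644 higher and 576 lower with arrays scaled to equal spread, and 515 higher and 539 lower with array weights.

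Among the other large rises with IL-13 were the cadherin CDH26 (2.56 ± 0.15), the inducible nitric oxide synthase NOS2 (2.31 ± 0.15), the transcription factor FOXA3 (2.27 ± 0.19), the cytokine IL19 (2.23 ± 0.17), SERPINB10 (2.15 ± 0.21), the carbonic anhydrase CA2 (2.06 ± 0.16) and the chloride channel ANO1 (1.81 ± 0.17). The matricellular protein POSTN rose by 1.67 ± 0.12 and SPDEF, a transcription factor of goblet cells, by 1.19 ± 0.12. The falls included BBOX1 (-1.53 ± 0.20), the plasminogen activator PLAT (-1.11 ± 0.11), IGFBP3 (-0.97 ± 0.15), FABP4 (-0.91 ± 0.12), the mTOR inhibitor DEPTOR (-0.90 ± 0.12), CLU (-0.86 ± 0.11), EDN2 (-0.86 ± 0.11), GSTA4 (-0.85 ± 0.11), RHOV (-0.84 ± 0.16) and IGFBP6 (-0.81 ± 0.10). FOXJ1, a master regulator of motile cilia, fell by 0.49 ± 0.08 (adjusted p = 0.0182). The intestinal mucin MUC2 (0.06 ± 0.11), CLCA1 (0.13 ± 0.09), FOXA2 (-0.04 ± 0.07), KRT5 (-0.20 ± 0.11), DUSP6 (0.10 ± 0.11) and TGFA (-0.12 ± 0.16) did not pass.

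The number of calls changed with the omission of single arrays, which also leaves 2 arrays in 1 group. The count was 138 without IL-13 replicate 1, 88 without IL-13 replicate 2, 52 without IL-13 replicate 3 and 227 without replicate 2 of both treatments. IL-13 replicate 3 was labelled with a control antibody and was also the only IL-13 array with treated RNA in Cy3, so these features cannot be separated. Over all features, IL-13 replicate 3 correlated at 0.259 and 0.0662 with IL-13 replicates 1 and 2. Replicates 1 and 2, which had the same labelling, correlated at 0.459 with each other. Without IL-13 replicate 3, 22 of the 41 named changes no longer passed, at adjusted p between 0.0578 and 0.589, among them CCL26 (adjusted p = 0.0578), PLAT (adjusted p = 0.0592) and S100A8 (adjusted p = 0.207). Some lost changes kept their size, such as CLU (-0.82) and RHOV (-0.81), and others shrank, such as S100A8 (-1.06) and CCL26 (2.80). Without IL-13 replicates 1 and 2 in turn, 16 and 17 of the 41 no longer passed, with adjusted p up to 0.255 and 0.2. Without anti-EGFR replicates 1, 2 and 3 in turn, 2, 3 and 1 were lost, with RHOV, DNAI1 or S100A9 among them and adjusted p up to 0.0814, and 2 and 1 were lost without replicates 2 and 3 of both treatments, with adjusted p up to 0.0776. ITLN1, FETUB, FCGBP, CDH26, NOS2, FOXA3, ALOX15, IL19, POSTN and SPDEF passed in every one of these omissions. With the control number as a block, S100A9 (adjusted p = 0.0532) and DNAI1 (adjusted p = 0.0541) did not pass.

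**Figure D2:**
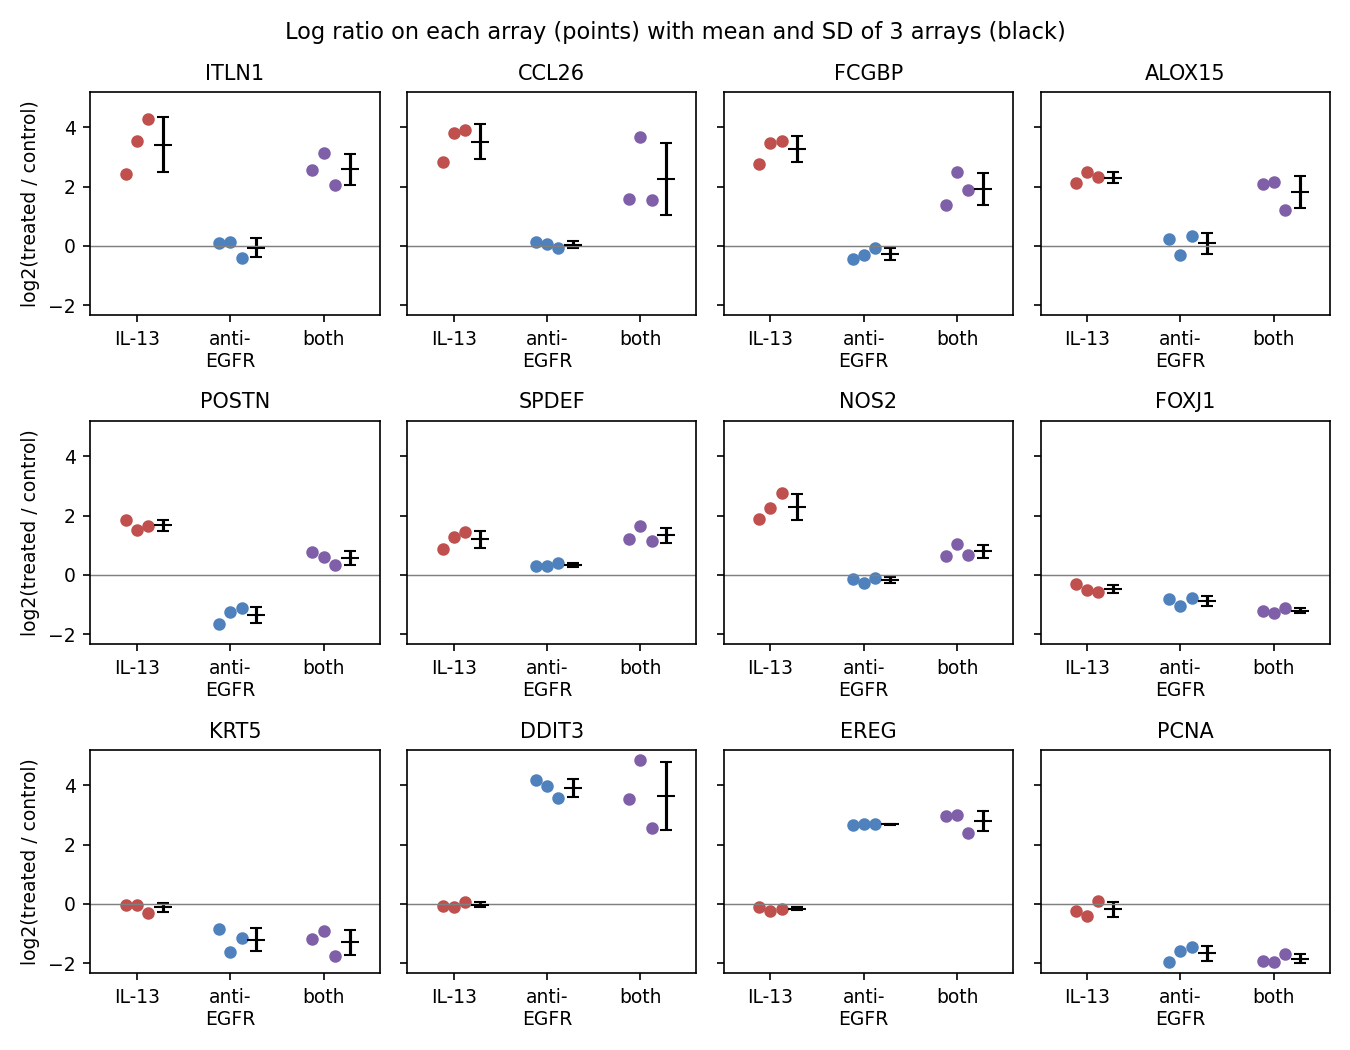
Log2 ratio of treated over control (y axis) on each of the 9 arrays for 12 genes, with 1 point per array and the mean and SD of the 3 arrays of a group in black. ITLN1, CCL26 and ALOX15 lie above 0 with IL-13 and with both treatments, DDIT3 and EREG lie above 0 and KRT5 and PCNA below 0 with the antibody and with both.

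In the IL-13 response list, 15 of 22 measured members were higher, 0 lower and 7 not passing (16 higher adjusted over the list alone), with a median of 1.25 log2 units. The IL-13 response list had adjusted p = 1.59e-95, and adjusted p = 0.0874 with an estimated correlation. This list also anchored the sign of the values and is not independent evidence of its direction. In the goblet and mucin list, 7 of 22 members were higher, 0 lower and 15 not passing (11 higher and 2 lower adjusted over the list alone), with FCGBP, FOXA3, SPDEF and GCNT3 (1.00 ± 0.09) among those higher. The goblet and mucin list had adjusted p = 1.17e-26, and adjusted p = 0.0874 with an estimated correlation. In the ciliated cell list, 5 of 27 members were lower and 22 did not pass (6 lower adjusted over the list alone), including TPPP3 (-0.59 ± 0.07), CAPS (-0.58 ± 0.09) and the dynein chain DNAI1 (-0.38 ± 0.07), at a median of -0.19. The ciliated cell list had adjusted p = 4.99e-13, and adjusted p = 0.0874 with an estimated correlation. FOXJ1, CAPS and DNAI1 lost their calls without each IL-13 array in turn (adjusted p between 0.0605 and 0.305), and TPPP3 lost its call without IL-13 replicates 2 and 3 (adjusted p = 0.058 and 0.109). In the ion transport list, 6 of 19 members were higher, 2 lower and 11 not passing (7 and 4 adjusted over the list alone), with CA2, ANO1 and the potassium channel KCNJ16 (1.19 ± 0.11) higher and the water channel AQP5 (-0.61 ± 0.08) lower. The ion transport list had adjusted p = 3.13e-06, and adjusted p = 0.218 with an estimated correlation. The median of the ion transport list was 0.01. In the mesenchymal list, POSTN was the 1 member of 10 that was higher and 9 did not pass, also adjusted over the list alone. The mesenchymal list had adjusted p = 0.00123, and adjusted p = 0.539 with an estimated correlation. CLCA1, FCGBP, GCNT3, SPDEF and TFF3 of the goblet and mucin list, SLC26A4 of the ion transport list and POSTN are also members of the IL-13 response list, so these 3 lists are not independent of the anchor either.

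Smaller shifts with IL-13 were called in 5 further lists, each from few passing members. In the squamous list, 1 of 28 members was higher, SERPINB13 (0.75 ± 0.11), 2 were lower, S100A8 and S100A9 (-0.52 ± 0.10), and 25 did not pass (2 and 5 adjusted over the list alone). The squamous list had adjusted p = 0.0248, and adjusted p = 0.559 with an estimated correlation. In the club and secretory list, 2 of 13 were higher, the immunoglobulin transporter PIGR (0.92 ± 0.08) and TSPAN8 (1.23 ± 0.17), and 11 did not pass (3 higher and 2 lower adjusted over the list alone). The club and secretory list had adjusted p = 0.0393, and adjusted p = 0.714 with an estimated correlation. In the ERK output list, 2 of 27 were lower, the protease MMP9 (-0.73 ± 0.10) and FOS (-0.58 ± 0.09), and 25 did not pass (2 lower adjusted over the list alone). The ERK output list had adjusted p = 0.00282, and adjusted p = 0.218 with an estimated correlation. The cholesterol synthesis list had 0 of 18 members passing (1 lower adjusted over the list alone) at a median of -0.15 (adjusted p = 0.0393, and adjusted p = 0.621 with an estimated correlation). The cell cycle list had 0 of 31 passing at a median of -0.05, also adjusted over the list alone (adjusted p = 0.025, and adjusted p = 0.621 with an estimated correlation). Without IL-13 replicate 3, the shifts of the squamous (adjusted p = 0.431), club and secretory (adjusted p = 0.794) and ERK output (adjusted p = 0.179) lists were lost and the median of cholesterol synthesis turned to 0.0475, and the control number as a block ended those of the squamous (adjusted p = 0.158) and club and secretory (adjusted p = 0.781) lists. The club and secretory shift was also lost without IL-13 replicate 2 (adjusted p = 0.102), anti-EGFR replicate 3 (adjusted p = 0.057) and replicates 1 and 3 of both treatments (adjusted p = 0.0604 and 0.134), and the cell cycle shift without IL-13 replicates 1 and 2 (adjusted p = 0.0563 and 0.0824). The squamous and cholesterol synthesis shifts were lost without replicate 3 of both treatments (adjusted p = 0.109 and 0.0677) and without a dye term (adjusted p = 0.0536 and 0.128), and cholesterol synthesis also without anti-EGFR replicate 1 (adjusted p = 0.0604). Of the 9 lists with no call, the interferon response, inflammatory mediators, heat shock, and leukocyte and endothelial lists had a median, mean or test of differing sign. IFI44L (-0.51 ± 0.07) in the interferon response list and ASNS (-0.39 ± 0.06) in the ER protein folding list fell, and the largest changes of the basal cell list, DST (0.35 ± 0.11) and ITGA6 (-0.25 ± 0.12), did not pass.

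The anti-EGFR antibody alone changed far more features than IL-13 alone, in both directions. DDIT3, a transcription factor of the stress response, rose by 3.82 ± 0.30, 14.1-fold (adjusted p = 2.28e-05), the stress cytokine GDF15 by 3.77 ± 0.35 and the pseudokinase TRIB3 by 3.61 ± 0.19 (adjusted p = 4.19e-06). EREG, a ligand of EGFR, rose by 2.67 ± 0.11. The splicing factor SFPQ fell by 2.97 ± 0.14 (adjusted p = 3.6e-06), and MAT2A, which makes S-adenosylmethionine, fell by 2.89 ± 0.16. In all, 3662 features were higher and 4056 lower, 34.4% of those tested, and 969 changed at least 2-fold.

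Further rises with the antibody were HSPA13 (2.56 ± 0.15), the uridine phosphorylase UPP1 (2.46 ± 0.17), KLHL36 (2.42 ± 0.10), osteopontin SPP1 (2.41 ± 0.22), the zinc exporter SLC30A1 (2.36 ± 0.08) and ANKHD1 (2.33 ± 0.11). The clock repressor NR1D1 rose 6.07-fold and RREB1 rose 5.67-fold. Further falls were the lipid-binding protein FABP5 (-2.61 ± 0.08), BCLAF1 (-2.53 ± 0.18), ENC1 (-2.46 ± 0.14), ARRDC3 (-2.46 ± 0.19), the chemokine CXCL6 (-2.30 ± 0.19), the histone gene H2AC6 (-2.23 ± 0.14), CAPN13 (-2.17 ± 0.18), the matricellular protein CCN2 (-2.10 ± 0.36), the death ligand TNFSF10 (-2.08 ± 0.14) and CCDC3 (-2.04 ± 0.22). POSTN fell by 1.35 ± 0.12, FOXJ1 by 0.90 ± 0.08 and the basal keratin KRT5 by 1.28 ± 0.11, while DUSP6, a phosphatase of ERK, rose by 0.77 ± 0.11. FOXA2 rose by 0.19 ± 0.07 (adjusted p = 0.0482). MUC2 (0.10 ± 0.11), CLCA1 (-0.03 ± 0.09), CCL26 (-0.04 ± 0.35), ALOX15 (0.02 ± 0.16), SPDEF (0.33 ± 0.12) and TGFA (0.14 ± 0.16) did not pass. Without anti-EGFR replicate 2, 4994 features passed. FOXA2 lost its call when any array except replicate 3 of both treatments was left out, and also with the control number as a block (adjusted p = 0.0741) or without a dye term (adjusted p = 0.051). CDH26 (-0.58 ± 0.15) lost its call without each anti-EGFR array in turn, and CD74 without anti-EGFR replicate 2, where 8 of 94 named changes were lost at adjusted p up to 0.301.

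Genes of cell division fell together with the antibody. In the cell cycle list, 21 of 31 members were lower, 0 higher and 10 not passing (22 lower adjusted over the list alone), at a median of -0.42. The cell cycle list had adjusted p = 4.95e-06, and adjusted p = 0.188 with an estimated correlation. Examples were the sliding clamp PCNA (-1.64 ± 0.10), the mitotic cyclin CCNB1 (-1.41 ± 0.12), UBE2C (-1.05 ± 0.09) and RRM2 (-0.97 ± 0.09). In the ciliated cell list, 14 of 27 members were lower, 3 higher and 10 not passing (14 lower and 4 higher adjusted over the list alone), with RSPH1 (-1.33 ± 0.09), NEK11 (-1.33 ± 0.09) and CAPS (-1.09 ± 0.09) lower. The ciliated cell list had adjusted p = 4.88e-05, and adjusted p = 0.188 with an estimated correlation. In the basal cell list, 7 of 13 were lower, 3 higher and 3 not passing (7 and 3 adjusted over the list alone), with KRT14 (-1.82 ± 0.09) and CAV1 (-1.22 ± 0.09) lower and the laminin chain LAMB3 (0.96 ± 0.10) higher. The basal cell list had adjusted p = 0.0132, and adjusted p = 0.188 with an estimated correlation. In the club and secretory list, 7 of 13 were lower, 1 higher and 5 not passing (8 lower and 1 higher adjusted over the list alone), with BPIFB1 (-0.90 ± 0.14) and BPIFA1 (-0.65 ± 0.09) lower, at a median of -0.53. The club and secretory list had adjusted p = 0.0342, and adjusted p = 0.235 with an estimated correlation. The club and secretory shift was lost without anti-EGFR replicate 2 (adjusted p = 0.0745) and without replicate 3 of both treatments (adjusted p = 0.0504).

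The shifts of 5 lists with the antibody were upward, each with members that fell or did not pass. In the NRF2 and xenobiotic list, 11 of 14 members were higher, 1 lower and 2 not passing (12 higher and 2 lower adjusted over the list alone), with CYP1B1 (2.19 ± 0.13), the glutathione enzyme subunit GCLM (1.55 ± 0.12) and the thioredoxin reductase TXNRD1 (1.31 ± 0.10) higher. The NRF2 and xenobiotic list had adjusted p = 2.53e-07, and adjusted p = 0.188 with an estimated correlation. In the ERK output list, genes that respond to ERK signaling, 14 of 27 were higher, 2 lower and 11 not passing (14 and 2 adjusted over the list alone), with JUN (1.47 ± 0.08), DUSP1 (1.48 ± 0.10) and DUSP4 (1.01 ± 0.06) higher. The ERK output list had adjusted p = 3.78e-05, and adjusted p = 0.188 with an estimated correlation. JUN encodes an AP-1 subunit that stress kinases also act on, and DUSP1 and DUSP4 encode phosphatases of MAP kinases. In the inflammatory mediators list, 12 of 20 were higher, 3 lower and 5 not passing (12 and 3 adjusted over the list alone), with the NF-kappaB inhibitor NFKBIA (1.67 ± 0.11), CXCL2 (1.53 ± 0.14) and IL1RN (1.28 ± 0.12) higher and CXCL6 lower. The inflammatory mediators list had adjusted p = 0.000909, and adjusted p = 0.188 with an estimated correlation. In the ER protein folding list, 8 of 17 were higher, 3 lower and 6 not passing (10 and 3 adjusted over the list alone), with TRIB3, DDIT3, ASNS (0.79 ± 0.06) and DNAJB9 (0.88 ± 0.07) higher. The ER protein folding list had adjusted p = 0.00243, and adjusted p = 0.188 with an estimated correlation. TRIB3, DDIT3 and ASNS are targets of the transcription factor ATF4 and not chaperones. In the cholesterol synthesis list, 7 of 18 were higher, 2 lower and 9 not passing (9 and 3 adjusted over the list alone), with INSIG1 (1.84 ± 0.15), MSMO1 (1.41 ± 0.12) and STARD4 (1.36 ± 0.10) higher. The cholesterol synthesis list had adjusted p = 0.0141, and adjusted p = 0.443 with an estimated correlation. The cholesterol synthesis shift was lost without anti-EGFR replicate 2 (adjusted p = 0.0745).

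The other lists showed no call with the antibody by cameraPR at the preset correlation, although members changed. Of all 12386 named genes, 2520 were higher and 2809 lower with the antibody, so changed members alone do not mark a list. The EGFR ligands and receptors list had 3 of 11 members higher, EREG, EGF (1.02 ± 0.09) and ERRFI1 (0.45 ± 0.09), and 2 lower, among them LRIG1 (-0.73 ± 0.10), the same adjusted over the list alone (adjusted p = 0.0504). The IL-13 response list had 2 of 22 higher and 3 lower (1 and 3 adjusted over the list alone), with TFF3 (-1.12 ± 0.11) and POSTN lower and SOCS1 (0.49 ± 0.09) higher (adjusted p = 0.648). The goblet and mucin list had 3 of 22 higher and 6 lower, with MUC13 (0.93 ± 0.07) higher and GALNT6 (-0.89 ± 0.08) lower. The interferon response list had 8 of 26 higher, such as MX2 (1.85 ± 0.13) and IFIT1 (1.20 ± 0.09), and 7 lower, such as OAS1 (-0.96 ± 0.10). Both of these lists had a median, mean or test of differing sign. The heat shock list had 5 of 8 lower and 1 higher (adjusted p = 0.101), with HSPA1A (-0.63 ± 0.08) lower and HSPD1 (0.48 ± 0.07) higher. The squamous list had 5 of 28 higher and 7 lower, with KRT4 (-1.75 ± 0.17) lower and RHCG (1.47 ± 0.22) higher. The ion transport list had 5 of 19 higher and 5 lower, with AQP4 (2.14 ± 0.15) higher and FXYD3 (-1.32 ± 0.14) lower. Of the markers of other cell types, the mesenchymal list had 1 of 10 higher and 4 lower, and the leukocyte and endothelial list had 4 of 8 higher and 1 lower, with CD68 (1.53 ± 0.16) and CD14 (0.79 ± 0.11) higher. The MHC class II list had 3 of 5 lower, including CD74 (-0.42 ± 0.09).

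**Figure D3:**
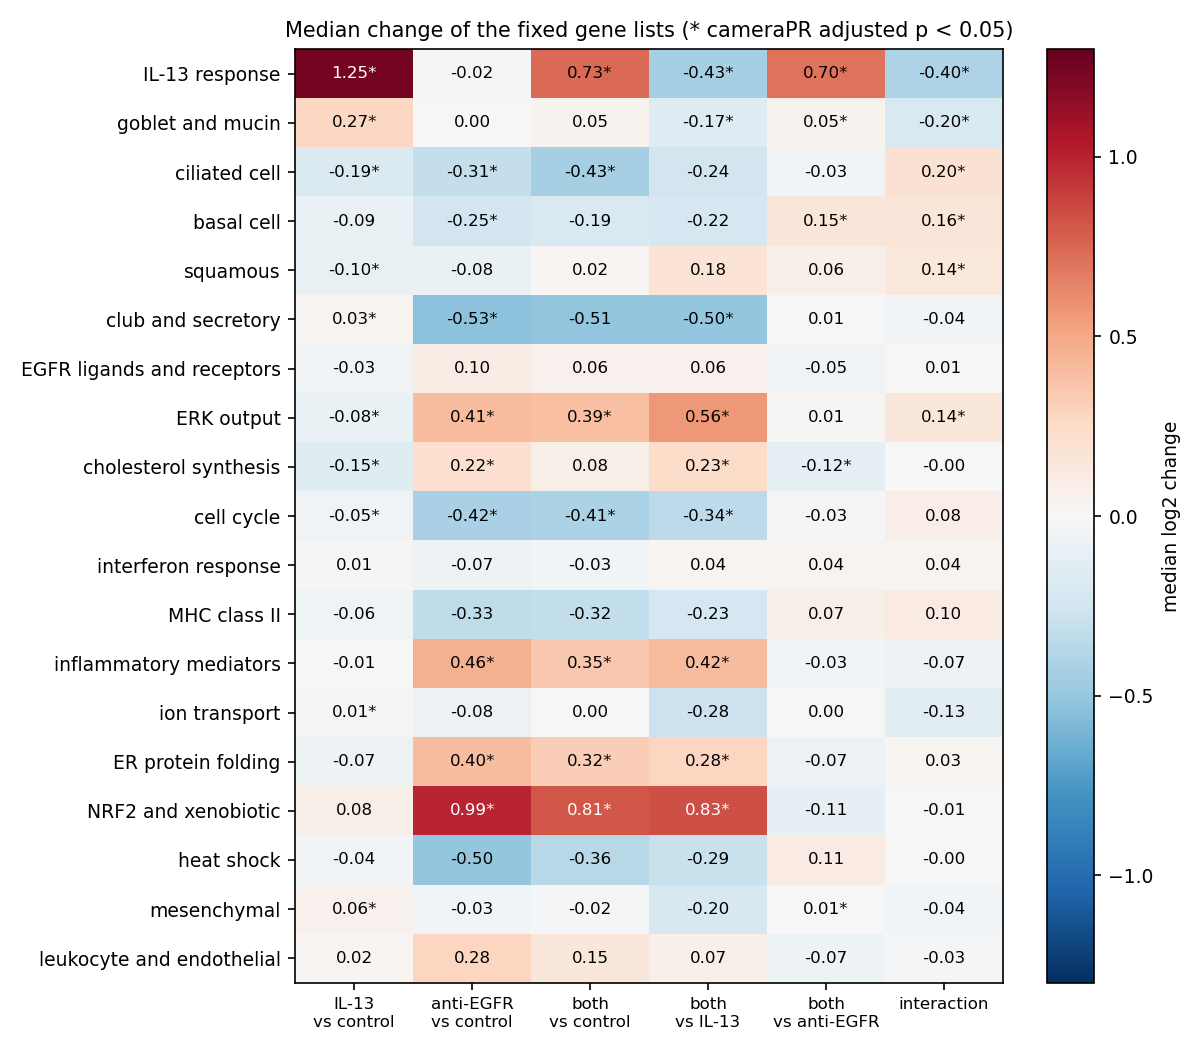
Median log2 change of the measured members of each of the 19 gene lists (vertical axis) in the 6 comparisons (horizontal axis), red for higher and blue for lower, with an asterisk where cameraPR gave an adjusted p under the threshold at the preset correlation. The IL-13 response list had a median of 1.25 with IL-13, -0.02 with the antibody and 0.73 with both treatments, and the NRF2 and xenobiotic list had 0.08, 0.99 and 0.81.

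With both treatments, cells showed the large changes of the antibody together with part of the IL-13 response. DDIT3 rose by 3.74 ± 0.30, 13.3-fold (adjusted p = 2.41e-05), TRIB3 by 3.36 ± 0.19 and SPP1 by 3.20 ± 0.22, next to IL19 with 2.65 ± 0.17 (adjusted p = 9.16e-06) and ITLN1 with 2.54 ± 0.31 (adjusted p = 0.000201). MAT2A fell by 3.08 ± 0.16 (adjusted p = 3.55e-06), CCN2 by 2.95 ± 0.36 and S100A8 by 2.20 ± 0.23. In all, 3686 features were higher and 4448 lower than in the control, 36.3% of those tested, and 1058 changed at least 2-fold. Other large rises were the retinoic acid hydroxylase CYP26B1 (2.83 ± 0.43), EREG (2.80 ± 0.11), GDF15 (2.68 ± 0.35), NR1D1 (2.66 ± 0.12), RREB1 (2.64 ± 0.14), thrombomodulin THBD (2.61 ± 0.10) and UPP1 (2.55 ± 0.17). Other large falls were SFPQ (-2.79 ± 0.14), ARRDC3 (-2.77 ± 0.19), BCLAF1 (-2.59 ± 0.18), FABP5 (-2.57 ± 0.08), ENC1 (-2.38 ± 0.14), BRPF1 (-2.32 ± 0.23), CAPN13 (-2.25 ± 0.18), LRP11 (-2.18 ± 0.11) and BBOX1 (-2.13 ± 0.20).

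Of the genes named in advance, CCL26 (2.35 ± 0.35), ALOX15 (1.87 ± 0.16), SPDEF (1.34 ± 0.12), DUSP6 (0.92 ± 0.11), POSTN (0.57 ± 0.12) and TGFA (0.46 ± 0.16) rose with both treatments, and FOXJ1 (-1.19 ± 0.08) and KRT5 (-1.22 ± 0.11) fell. MUC2 (0.07 ± 0.11), CLCA1 (-0.03 ± 0.09) and FOXA2 (0.10 ± 0.07) did not pass. Without replicate 2 of both treatments, 5023 features passed and 9 of 93 named changes were lost at adjusted p up to 0.359, among them those of POSTN, TGFA and CD14. TGFA also did not pass with any of 5 further arrays left out in turn, the 3 IL-13 arrays, anti-EGFR replicate 1 and replicate 1 of both treatments, at adjusted p up to 0.237. ACTA2 (-0.34 ± 0.11) lost its call without each of 6 arrays in turn, and it did not pass with the control number as a block (adjusted p = 0.0675). A fit of only the arrays with both treatments gave 4556 features.

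In the IL-13 response list, 15 of 22 members were higher with both treatments, 1 lower and 6 not passing, the same adjusted over the list alone for higher and lower, with FCGBP (1.94 ± 0.20) and CDH26 (1.60 ± 0.15) among those higher. The test of this list gave adjusted p = 5.75e-05, and adjusted p = 0.35 with an estimated correlation. In the cell cycle list, 23 of 31 were lower, 0 higher and 8 not passing (24 lower adjusted over the list alone), with PCNA (-1.88 ± 0.10) and CCNB1 (-1.63 ± 0.12) lower. The cell cycle list had adjusted p = 6.54e-06, and adjusted p = 0.328 with an estimated correlation. In the ciliated cell list, 15 of 27 were lower, 2 higher and 10 not passing (16 and 2 adjusted over the list alone), with NEK11 (-1.48 ± 0.09) and RSPH1 (-1.34 ± 0.09) lower. The ciliated cell list had adjusted p = 2.1e-05, and adjusted p = 0.328 with an estimated correlation. In the ERK output list, 16 of 27 were higher, 4 lower and 7 not passing (16 and 6 adjusted over the list alone), with DUSP1 (1.63 ± 0.10) and JUNB (1.37 ± 0.11) higher. The ERK output list had adjusted p = 4.36e-05, and adjusted p = 0.328 with an estimated correlation. In the NRF2 and xenobiotic list, 8 of 14 were higher, 1 lower and 5 not passing (8 and 2 adjusted over the list alone), with TXNRD1 (1.51 ± 0.10) and SLC7A11 (1.10 ± 0.09) higher. The NRF2 and xenobiotic list had adjusted p = 4.37e-06, and adjusted p = 0.328 with an estimated correlation. In the inflammatory mediators list, 11 of 20 were higher, 3 lower and 6 not passing (12 and 3 adjusted over the list alone), with NFKBIA (1.64 ± 0.11) and IL1B (2.11 ± 0.17) higher. The inflammatory mediators list had adjusted p = 0.0015, and adjusted p = 0.328 with an estimated correlation. In the ER protein folding list, 9 of 17 were higher, 3 lower and 5 not passing (9 and 4 adjusted over the list alone), with DNAJB9 (0.88 ± 0.07) higher and CRELD2 (-0.92 ± 0.08) lower. The ER protein folding list had adjusted p = 0.044, and adjusted p = 0.35 with an estimated correlation. The ER protein folding shift was lost without IL-13 replicate 2 (adjusted p = 0.0563) and without replicate 1 of both treatments (adjusted p = 0.0883). The squamous and interferon response lists, neither of them called, had a median, mean or test of differing sign.

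The effect of the antibody on cells that received IL-13, read from both treatments against IL-13, covered 5340 features. TRIB3 rose by 4.16 ± 0.27, 17.9-fold (adjusted p = 6.87e-05), DDIT3 by 3.86 ± 0.44 and EREG by 2.98 ± 0.15. MAT2A fell by 3.14 ± 0.22 (adjusted p = 8.72e-05), CCN2 by 2.82 ± 0.53 and SFPQ by 2.70 ± 0.20. Of the genes that IL-13 raised, NOS2 fell by 1.53 ± 0.21 (adjusted p = 0.00112), POSTN by 1.10 ± 0.18 and KCNJ16 by 1.76 ± 0.15. Such a fall need not mean a smaller rise with IL-13. POSTN also fell with the antibody alone (-1.35 ± 0.12), and IL-13 raised POSTN by 1.92 ± 0.18 with the antibody and 1.67 ± 0.12 without it. For NOS2 these rises were 0.96 ± 0.21 and 2.31 ± 0.15, and neither difference passed. In all, 2365 features were higher and 2975 lower, 23.8% of those tested, and 1095 changed at least 2-fold. Of the 230 features that IL-13 raised, 78 were lower and 59 higher with the antibody alone against control, a comparison that shares its controls with the IL-13 calls. Over all 22431 features, the antibody alone gave 4056 lower and 3662 higher.

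Further rises against IL-13 were CYP26B1 (3.15 ± 0.61), GDF15 (3.03 ± 0.51), UPP1 (2.79 ± 0.25), HSPA13 (2.77 ± 0.21), SPP1 (2.64 ± 0.32), RREB1 (2.63 ± 0.20), NR1D1 (2.59 ± 0.18), the homeobox factor DLX2 (2.57 ± 0.18) and the neurotrophic factor ARTN (2.48 ± 0.18). Further falls were ARRDC3 (-2.77 ± 0.27), BCLAF1 (-2.67 ± 0.26), ENC1 (-2.37 ± 0.21), BRPF1 (-2.35 ± 0.33), the sulfate transporter SLC26A2 (-2.28 ± 0.22), CAPN13 (-2.18 ± 0.26), the immune checkpoint ligand VTCN1 (-2.16 ± 0.17), SLC16A9 (-2.16 ± 0.38) and LRP11 (-2.13 ± 0.16). FOXJ1 (-0.70 ± 0.11) and KRT5 (-1.02 ± 0.16) fell and DUSP6 (0.82 ± 0.17) rose. CCL26 (-1.08 ± 0.51), ALOX15 (-0.37 ± 0.24), SPDEF (0.14 ± 0.18), TGFA (0.58 ± 0.23), MUC2 (0.01 ± 0.16), CLCA1 (-0.16 ± 0.13) and FOXA2 (0.14 ± 0.09) did not pass. With arrays scaled to equal spread, SPDEF was lower (-0.66, adjusted p = 0.0381), and FOXJ1 (adjusted p = 0.391) and DUSP6 (adjusted p = 0.0943) did not pass. The count was 2779 without replicate 2 of both treatments, where CYP26B1 and CCN2 lost their calls among 9 of 87 at adjusted p up to 0.204, and 3502 without IL-13 replicate 3, where 7 of 87 were lost, CYP26B1, DUSP6 and GCNT3 among them, at adjusted p up to 0.188.

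In the IL-13 response list, at a median of -0.43 and of -1.27 with arrays scaled to equal spread, 6 of 22 members were lower with the antibody added, 0 higher and 16 not passing (7 lower adjusted over the list alone), with TFF3 (-1.65 ± 0.16), NOS2 and GCNT3 (-0.68 ± 0.14) among them. Its test gave adjusted p = 0.00739, adjusted p = 0.424 with an estimated correlation and adjusted p = 0.0602 with fry. This shift was lost without IL-13 replicate 3 (median -0.09, adjusted p = 0.128) and without replicate 3 of both treatments (median -0.24, adjusted p = 0.08). In the goblet and mucin list, 9 of 22 were lower, 2 higher and 11 not passing (9 and 2 adjusted over the list alone), with the mucin glycosyltransferases GALNT6 (-1.44 ± 0.11) and GALNT7 (-1.37 ± 0.17) lower. The goblet and mucin list had adjusted p = 0.00335, and adjusted p = 0.418 with an estimated correlation. In the club and secretory list, 5 of 13 were lower, 1 higher and 7 not passing (6 and 1 adjusted over the list alone), with BPIFB1 (-1.63 ± 0.21) and PIGR (-0.85 ± 0.11) lower. The club and secretory list had adjusted p = 0.0111, and adjusted p = 0.418 with an estimated correlation. In the cell cycle list, 11 of 31 were lower, 0 higher and 20 not passing (15 lower adjusted over the list alone), with PCNA (-1.74 ± 0.15) lower. The cell cycle list had adjusted p = 0.000435, and adjusted p = 0.418 with an estimated correlation. In the ERK output list, 16 of 27 were higher, 2 lower and 9 not passing (16 and 4 adjusted over the list alone), with DUSP1 (1.86 ± 0.14) and MYC (1.41 ± 0.14) higher. The ERK output list had adjusted p = 6.51e-07, and adjusted p = 0.32 with an estimated correlation. In the NRF2 and xenobiotic list, 9 of 14 were higher, 1 lower and 4 not passing (10 and 1 adjusted over the list alone), with SRXN1 (1.39 ± 0.19) higher. The NRF2 and xenobiotic list had adjusted p = 1.16e-05, and adjusted p = 0.367 with an estimated correlation. In the inflammatory mediators list, 10 of 20 were higher, 3 lower and 7 not passing, the same adjusted over the list alone, with IL1B (2.19 ± 0.25) higher. The inflammatory mediators list had adjusted p = 0.00335, and adjusted p = 0.367 with an estimated correlation. In the ER protein folding list, 7 of 17 were higher, 2 lower and 8 not passing (8 and 2 adjusted over the list alone), with ASNS (0.71 ± 0.09) higher. The ER protein folding list had adjusted p = 0.00632, and adjusted p = 0.367 with an estimated correlation. In the cholesterol synthesis list, 4 of 18 were higher, 2 lower and 12 not passing (6 and 2 adjusted over the list alone), with MSMO1 (1.49 ± 0.17) higher and FDPS (-0.59 ± 0.11) lower. The cholesterol synthesis list had adjusted p = 0.0269, and adjusted p = 0.428 with an estimated correlation. Without IL-13 replicate 3, the shifts of the goblet and mucin (adjusted p = 0.0545), club and secretory (adjusted p = 0.0574), inflammatory mediators (adjusted p = 0.0668) and cholesterol synthesis (adjusted p = 0.242) lists were lost, the last also without replicate 1 of both treatments (adjusted p = 0.073).

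The effect of IL-13 on cells that received the antibody, read from both treatments against anti-EGFR, gave 23 calls, most of them genes that IL-13 also raised alone. By limma, 1032 features had an unadjusted p under 0.05, where chance would give 1122. The median standard error was 0.12, against 0.08 for IL-13 against control, so the 2 counts do not compare the extent of the effect. IL19 rose by 3.00 ± 0.25, 8.01-fold (adjusted p = 0.00516), the salivary protein gene STATH by 2.43 ± 0.21 (adjusted p = 0.006), FCGBP by 2.25 ± 0.29 and CDH26 by 2.18 ± 0.22. POSTN rose by 1.92 ± 0.18 (adjusted p = 0.00901) and ALOX15 by 1.85 ± 0.24. The metabolic coactivator PPARGC1A fell by 1.33 ± 0.15 (adjusted p = 0.0172) and CYP4F2 by 0.75 ± 0.10. In all, 20 features were higher and 3 lower, and 18 of the 23 had been called in the same direction with IL-13 alone. The other named rises were CA2 (1.68 ± 0.23), the folate enzyme GGH (1.39 ± 0.11), the cytokine TNFSF13 (1.23 ± 0.12), PIP (1.19 ± 0.13) and the protease CTSC (1.11 ± 0.14), and CEP72 rose 2.46-fold. CCL26 (2.40 ± 0.51), SPDEF (1.01 ± 0.18), FOXJ1 (-0.29 ± 0.11), TGFA (0.32 ± 0.23), DUSP6 (0.14 ± 0.17), FOXA2 (-0.09 ± 0.09), KRT5 (0.06 ± 0.16), MUC2 (-0.03 ± 0.16) and CLCA1 (0.00 ± 0.13) did not pass. The count by limma was 0 without anti-EGFR replicate 2 and 0 without replicate 2 of both treatments, with 878 and 716 features at an unadjusted p under 0.05. Each of these arrays was the only one of its group in its dye orientation. In these fits all 14 named changes were lost, at adjusted p up to 0.428 and 0.449. It was 8, 10 and 10 without anti-EGFR replicate 1, anti-EGFR replicate 3 and IL-13 replicate 2, with 8, 7 and 6 of the 14 lost at adjusted p up to 0.173, 0.112 and 0.106. Without replicate 3 of both treatments 4 of the 14 were lost, without IL-13 replicate 3, 2 were lost, and without IL-13 replicate 1 or replicate 1 of both treatments CYP4F2 alone was lost, at adjusted p up to 0.089. With the control number as a block, ALOX15 (adjusted p = 0.0827) and CYP4F2 (adjusted p = 0.0596) did not pass. With arrays scaled to equal spread, 10 of the 14 were lost, at adjusted p up to 0.237, among them FCGBP (adjusted p = 0.108), POSTN (adjusted p = 0.054), ALOX15 (adjusted p = 0.0543) and CA2 (adjusted p = 0.093), and 6 were lost in a fit of only these groups, at adjusted p up to 0.174. Leaving out all arrays of control number 1 gave 0 calls, and leaving out those of control number 2 gave 20, of which 5 were higher and 15 lower and none was among the 23. Without control number 2, the anti-EGFR arrays all had treated RNA in Cy5 and those with both treatments in Cy3. Dye and treatment were then separated through the IL-13 arrays alone.

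In the IL-13 response list, 4 of 22 members were higher in this comparison, 0 lower and 18 not passing (12 higher adjusted over the list alone), at a median of 0.70. The IL-13 response list had adjusted p = 7.84e-40, adjusted p = 0.188 with an estimated correlation and adjusted p = 0.0999 with fry. In the goblet and mucin list, FCGBP was the 1 member of 22 that was higher and 21 did not pass (4 higher and 2 lower adjusted over the list alone). The goblet and mucin list had adjusted p = 0.00233, and adjusted p = 0.753 with an estimated correlation. In the mesenchymal list, POSTN was again the 1 higher member of 10 and 9 did not pass, also adjusted over the list alone. The mesenchymal list had adjusted p = 0.0213, and adjusted p = 0.788 with an estimated correlation. In the basal cell list, 0 of 13 passed (1 higher adjusted over the list alone), with KRT14 at 0.88 ± 0.13. The basal cell list had adjusted p = 0.00152, and adjusted p = 0.188 with an estimated correlation. In the cholesterol synthesis list, 0 of 18 passed, also adjusted over the list alone, at a median of -0.12. The cholesterol synthesis list had adjusted p = 0.0304, and adjusted p = 0.788 with an estimated correlation. The mesenchymal shift was lost with the control number as a block (adjusted p = 0.0883), without anti-EGFR replicates 1 and 2 (adjusted p = 0.0546 and 0.0742) and without replicate 1 of both treatments (adjusted p = 0.277). The cholesterol synthesis shift was lost without anti-EGFR replicates 1 and 2 (adjusted p = 0.166 and 0.603) and without replicates 2 and 3 of both treatments (adjusted p = 0.366 and 0.315), the goblet and mucin shift without replicate 2 of both treatments (adjusted p = 0.451), and the basal cell shift without anti-EGFR replicate 2 (adjusted p = 0.0573). The ERK output, interferon response and inflammatory mediators lists, none of them called, had a median, mean or test of differing sign.

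**Figure D4:**
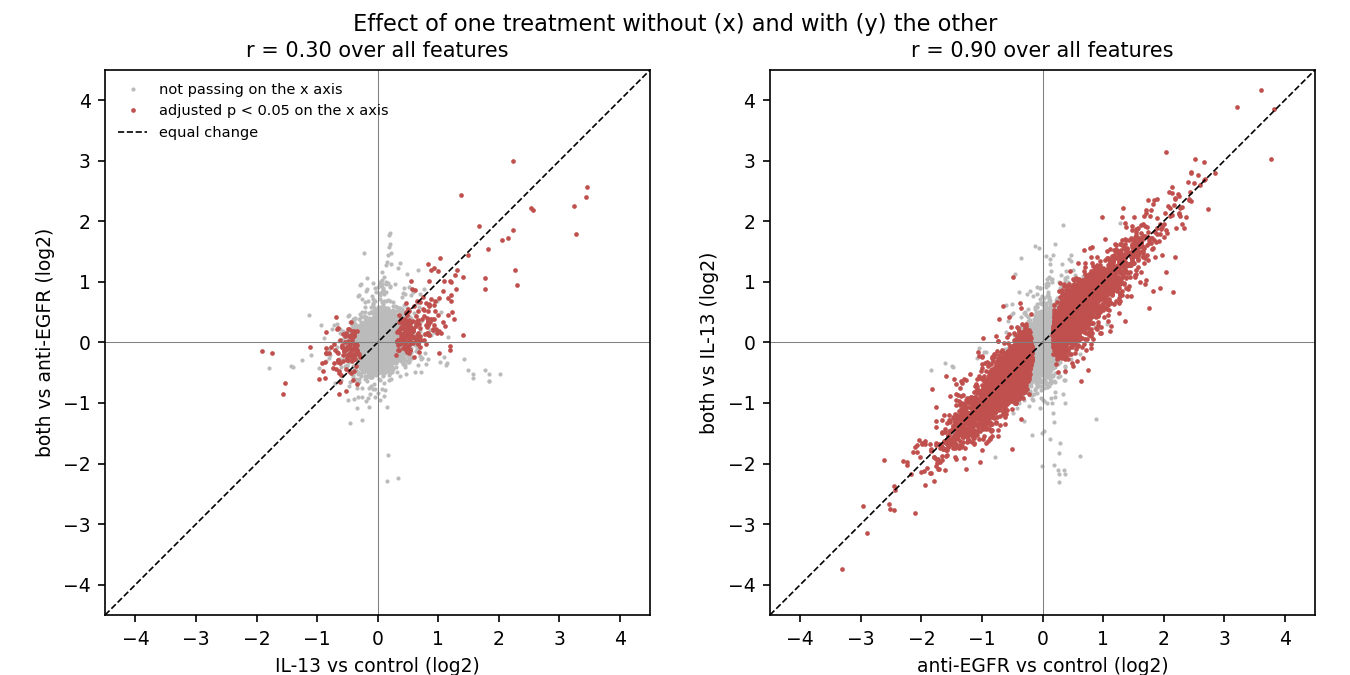
Log2 change of every feature without the other agent (x axis) and with it (y axis), for IL-13 on the left and for the antibody on the right, with features that passed on the x axis in red, the others in grey and a dashed line for equal change. The IL-13 changes correlate at 0.295 over all features and the antibody changes at 0.899. Among the features that passed on the x axis these values are 0.791 and 0.955.

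The difference between the IL-13 effect with and without the antibody did not pass for any feature by limma, with 0 calls, 988 features at an unadjusted p under 0.05 where chance would give 1122, and a smallest adjusted p of 0.117. Nearest to the threshold were S100P, a calcium-binding protein, with a difference of -1.32 ± 0.15 (adjusted p = 0.117), and DKK1, a Wnt antagonist, with 1.25 ± 0.14 (adjusted p = 0.117). KRT14 (1.05 ± 0.16), MED20 (0.69 ± 0.11), ACKR3 (0.65 ± 0.11), DAPK2 (0.73 ± 0.12), SLC39A8 (-0.90 ± 0.13), KCNJ16 (-1.25 ± 0.19), ERBIN (-0.66 ± 0.11) and TRIM16 (-0.63 ± 0.11) had the next smallest p values and did not pass either. Of the genes named in advance, CCL26 (-1.04 ± 0.63), TGFA (0.44 ± 0.28), ALOX15 (-0.39 ± 0.29), KRT5 (0.27 ± 0.20), POSTN (0.25 ± 0.22), FOXJ1 (0.20 ± 0.14), SPDEF (-0.18 ± 0.22), CLCA1 (-0.13 ± 0.17), MUC2 (-0.09 ± 0.19), FOXA2 (-0.05 ± 0.12) and DUSP6 (0.04 ± 0.21) did not pass. The count was 1 without a dye term, 25 with arrays scaled to equal spread and 181 with array weights.

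As groups, however, the lists of IL-13 differed between cells with and without the antibody at the preset correlation, with 0 members passing singly in every list. The IL-13 response list had a median difference of -0.40, with 3 of 22 members above 0 and 2 lower adjusted over the list alone (adjusted p = 8.22e-08, and adjusted p = 0.4 with an estimated correlation), and NOS2 (-1.35 ± 0.27) and GCNT3 (-0.81 ± 0.17) had the smallest p. That median was -1.04 with arrays scaled to equal spread and -0.21 without replicate 3 of both treatments. The goblet and mucin list had -0.20, with 2 lower adjusted over the list alone (adjusted p = 7.16e-08, and adjusted p = 0.286 with an estimated correlation) and FOXA3 at -1.07 ± 0.34. The ciliated cell list had 0.20, with 0 passing adjusted over the list alone (adjusted p = 1.04e-06, and adjusted p = 0.286 with an estimated correlation) and TPPP3 at 0.54 ± 0.13. The basal cell list had 0.16, with KRT14 the 1 member higher adjusted over the list alone (adjusted p = 0.00113, and adjusted p = 0.286 with an estimated correlation). The squamous list had 0.14, with 2 higher adjusted over the list alone (adjusted p = 0.00107, and adjusted p = 0.4 with an estimated correlation) and KRT13 at 0.60 ± 0.12. The ERK output list had 0.14, with 2 higher adjusted over the list alone (adjusted p = 0.0163, and adjusted p = 0.4 with an estimated correlation) and FOS at 0.73 ± 0.17 and EGR1 at 0.80 ± 0.20. Without IL-13 replicate 3 the differences of the squamous (adjusted p = 0.168) and ERK output (adjusted p = 0.481) lists were lost and the median of the IL-13 response list was -0.134, and both calls were lost without replicate 1 of both treatments (adjusted p = 0.0916 for each), the ERK output list also without anti-EGFR replicate 1 (adjusted p = 0.0551). The EGFR ligands and receptors, ER protein folding and heat shock lists, none of them called, had a median, mean or test of differing sign.

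The changes with 1 agent were then compared without and with the other, across features that are not independent replicates. The antibody changes correlated at 0.899 over all features (simulated groups without effect, -0.0563; covariance 0.177), with 7503 of the 7718 antibody calls, 97.2%, of the same sign in the presence of IL-13 and a slope of 0.975. The IL-13 changes correlated at 0.295 (simulated, -0.0528). Of the 343 IL-13 calls, 286, 83.4%, had the same sign in the presence of the antibody, with a slope of 0.554. Among the calls alone, the correlations were 0.791 for IL-13 and 0.955 for the antibody. These and both slopes were taken on features selected by their change without the other agent. IL-13 changed 1.53% of the features and the antibody 34.4%. The 2 correlations over all features therefore do not compare how far each effect was altered. Of the 230 features raised by IL-13, 197 were above 0 in both treatments against anti-EGFR, and of the 113 lowered 89 were below 0. The correlation of the IL-13 changes was 0.0819 and the share of the same sign 76.3% without anti-EGFR replicate 2.

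IL-13 and the antibody, each against control, shared 59 features that both raised and 56 that both lowered. Independent lists would share 37.5 and 20.4. Another 96 features were called in opposite directions, and no number for independent lists is given for these. Of the 343 IL-13 calls, 52.5% had the same sign with the antibody, so the overlap does not show a shared direction. S100P (1.20 ± 0.08 with IL-13 and 2.15 ± 0.08 with the antibody), the complement regulator CD55 (1.07 ± 0.09 and 1.08 ± 0.09), HDAC9 (0.66 ± 0.07 and 1.28 ± 0.07), TRIM16 (0.92 ± 0.06 and 0.56 ± 0.06) and HS3ST1 (0.85 ± 0.08 and 0.69 ± 0.08) rose with each, and PLAT (-1.11 ± 0.11 and -1.59 ± 0.11) fell with each. The amino acid transporter SLC6A14 (1.21 ± 0.09 and -1.58 ± 0.09), CTSC (1.28 ± 0.10 and -1.13 ± 0.10), POSTN (1.67 ± 0.12 and -1.35 ± 0.12) and PIP (0.87 ± 0.09 and -1.09 ± 0.09) rose with IL-13 and fell with the antibody. Over all features these changes correlated at 0.00204, where groups without effect that share their controls gave 0.513 in simulations that assigned equal variance to treated and control samples. The simulated groups held no treatment variance, so observed and simulated correlations are not on the same scale. The covariance was 0.00015, against 0.0053 in these simulations. Shared calls numbered 16 without IL-13 replicate 3 against 115 with all arrays. The antibody alone and both treatments shared 2995 higher and 3596 lower features (independent lists, 602 and 804), and 11 were opposite. Their changes correlated at 0.926 over all features, against 0.455 in these simulations, with a covariance of 0.177 against 0.0047. IL-13 alone and both treatments shared 113 higher and 68 lower features (independent lists, 37.8 and 22.4), 41 in all without IL-13 replicate 3, and 52 were opposite. Their changes correlated at 0.114 over all features, against 0.457 in these simulations. Their covariance of 0.0087 was above the simulated 0.0047, so the lower correlation does not show that these groups share less than groups without effect. Because the comparisons share controls, the numbers for independent lists are not those that groups without effect would give.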

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

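The random assignment of arrays to groups and the bootstrap criterion for single arrays were chosen only after the results were seen. The IL-13 effect with the antibody differed from the IL-13 effect without it in 6 gene lists, by a test of the difference itself at the preset correlation. The median difference was -0.40 log2 units for the IL-13 response list, -0.20 for the goblet and mucin list, 0.20 for the ciliated cell list, 0.16 for the basal cell list, 0.14 for the squamous list and 0.14 for the ERK output list. None of the 6 held with an estimated correlation, where adjusted p lay between 0.286 and 0.4, and 0 single features passed by limma, with 988 at an unadjusted p under 0.05. Of 100 assignments of the 9 arrays to the groups, the real one included, 100 gave at least the real count of 0, and the highest other count was 62. Every assignment reaches a count of 0, so this number says nothing about chance.

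In the IL-13 response list, the estimated difference was below 0 for 19 of 22 members, none of which passed on its own. The 19 include CCL11, CCL24, HSD3B1, CLCA1 and SOCS1, which did not pass with IL-13 alone, and the list call did not hold with an estimated correlation (adjusted p = 0.4). Smaller estimates with the antibody may reflect the choice of genes, a single array or the antibody. Choice by the IL-13 arrays would leave a ratio near 1 on arrays not used for the choice, and for 200 features chosen on 2 IL-13 arrays the change with the antibody was on average 0.327 of the change on the third array, with 0.371, 0.277 and 0.333 for the 3 arrays, which argues against it. A single array cannot be told apart from an effect of the antibody, because the median difference of the list was nearest to 0, at -0.13, without IL-13 replicate 3. Its bootstrap interval over members ran from -0.25 to 0.01. The criterion planned before the results would have counted this median as speaking against a single array. The later bootstrap resampled members, which are not replicates. The median difference was -0.21 without replicate 3 of both treatments and -1.04 with arrays scaled to equal spread. With all arrays of control number 1, 2 or 3 left out it was -0.61, -0.97 and -0.08, with 18, 19 and 14 of 22 members below 0. An interaction between the treatments, which the design names, stays open. So do the control antibody that the label gives for IL-13 replicate 3 and the dye orientation of that array, the only IL-13 array with treated RNA in Cy3.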

How the results depend on the processing

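The omission of all arrays of a control number was chosen after seeing the data, and all other alternatives were planned. Of 329 named gene results past the threshold, 258 passed in the same direction under every alternative run for genes, 71 lost the threshold under at least 1, and 0 turned. Single probes, other thresholds, the other reading of the direction and the omission of a control number were not run for genes. No named result could pass under the other reading, nor for both treatments against anti-EGFR without control number 1, since 0 features were called there. No value was missing, so another treatment of missing values had nothing to change. The cause of the shifts below was not tested. Without control number 2, the anti-EGFR group and the group with both treatments each kept 1 dye orientation, and the dye term rested on the IL-13 arrays. The IL-13 group kept 1 orientation without control number 3. Counts without these control numbers therefore cannot separate a control sample from the dyes.

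The number of features changed by IL-13 against control, 343, became 1220 with arrays scaled to equal spread (52.8% higher against 67.1%), 1054 with array weights (48.9% higher), 1072 with only the IL-13 arrays fitted, 530 at an adjusted p under 0.10 and 47 with a change of at least 2-fold. Leaving out all arrays of control number 1, 2 or 3 gave 72, 101 and 73. For anti-EGFR against control, 7718 became 5107 and 1817 without control numbers 1 and 2 and 969 with a 2-fold change. For both treatments against control, 8134 became 4556 with only their arrays fitted, 5396 and 1327 without control numbers 1 and 2, and 1058 with a 2-fold change. For both treatments against IL-13, 5340 became 9620 with array weights, 2297 and 278 without control numbers 1 and 2, and 1095 with a 2-fold change. For both treatments against anti-EGFR, 23 became 5 with scaled arrays, 138 with array weights, 14 with only these groups fitted, 0 without control number 1, where limma gave 813 at an unadjusted p under 0.05, and 20 without control number 2, with 5 higher and 15 lower against 20 and 3 and none of the 23 kept. The interaction count of 0 became 1 without a dye term, 25 with scaled arrays, 181 with array weights and 29 without control number 2. With the control number as a block the 6 counts were 406, 8241, 8540, 5751, 23 and 0.

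With each array left out in turn, counts ranged from 52 to 411 for IL-13, from 4994 to 8328 for anti-EGFR, from 5023 to 8183 for both, from 2779 to 6135 for both against IL-13, from 0 to 25 for both against anti-EGFR, and from 0 to 0 for the interaction. Lists shifted numbered 6 to 10, 8 to 10, 6 to 8, 4 to 10, 2 to 7 and 5 to 8 in the same order. The correlation of IL-13 changes without and with the antibody ranged from 0.0819 to 0.344 and the share of calls with the same sign from 76.3% to 94.2%. For the antibody changes these ranges were 0.828 to 0.904 and 96.7% to 98.4%. Shared calls ranged from 16 to 152 for IL-13 and anti-EGFR, from 41 to 214 for IL-13 and both, and from 4526 to 6765 for anti-EGFR and both.

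Of 46 list shifts, 46 were lost with an estimated correlation, which leaves 0 lists in each of the 6 comparisons, 18 were lost with fry, 3 with the control number as a block and 2 without a dye term. With fry, 4 lists were called for IL-13, 13 for both against control, 1 for both against anti-EGFR and 0 for the interaction. The 1 list for both against anti-EGFR was the basal cell list and not the IL-13 response list.

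Under the other reading of the direction, limma called 0 features in each comparison, with 1256, 503, 530, 349, 139 and 350 at an unadjusted p under 0.05 in the order above, and 1, 0, 0, 1, 2 and 1 lists. Its medians had the opposite test direction in these cases, in log2 units. For IL-13 they were -0.0244 for IL-13 response, -0.00375 for goblet and mucin, 0.085 for squamous, -0.0332 for club and secretory, 0.107 for cholesterol synthesis, 0.0535 for cell cycle, -0.0055 for ion transport and -0.295 for NRF2 and xenobiotic. The cholesterol synthesis median with IL-13 ranged from -0.178 to 0.0475 with each array left out, and it turned without IL-13 replicate 3. For anti-EGFR they were -0.00108 for ciliated cell and 0.0692 for inflammatory mediators. For both against control they were 0.0508 for ciliated cell, -0.0406 for ERK output, 0.0241 for cell cycle and -0.0105 for inflammatory mediators. For both against IL-13 they were 0.0838 for IL-13 response, 0.101 for goblet and mucin, 0.131 for club and secretory, -0.013 for ERK output, -0.113 for cholesterol synthesis and -0.00377 for inflammatory mediators. For the interaction they were 0.195 for IL-13 response, 0.118 for goblet and mucin, -0.113 for basal cell, -0.197 for squamous and -0.050 for ERK output. The gene SPDEF in both against IL-13, not passing before, was lower at -0.66 with scaled arrays.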

Other observations

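The gene families and the tests in this part were chosen after the results were seen, except the other sign patterns and splits of the arrays. Of 10 families tried with the anti-EGFR antibody, those not called were the zinc finger genes named ZNF (adjusted p = 0.551), complex I subunits (adjusted p = 0.572), ER chaperones (adjusted p = 0.238) and the cytosolic and mitochondrial tRNA synthetases (adjusted p = 0.076 for each). The clock, splicing factor and ATF4 families were chosen with the large changes in view, so their counts are given without a test. Of 9 measured clock output genes, 5 were higher and 1 lower with the antibody, among them DBP (2.17 ± 0.11), PER1 (1.31 ± 0.14) and CIART (1.15 ± 0.12), at a median of 0.39 log2 units. Of 11 serine and arginine rich splicing factors, 8 were lower and 1 higher, with SRSF5 (-1.93 ± 0.14), SRSF1 (-1.68 ± 0.25) and SRSF3 (-1.52 ± 0.14) lower and SRSF11 (0.57 ± 0.08) higher, at a median of -0.94. Of 30 proteasome subunits, 14 were lower and 1 higher, including PSMD12 (-1.19 ± 0.17) and PSMC3 (-0.77 ± 0.08), at a median of -0.25 (adjusted p = 0.0037, and adjusted p = 0.16 with an estimated correlation). Of 52 cytosolic ribosomal proteins, 19 were higher and 6 lower, with RPL17 (1.50 ± 0.11) higher and RPS26 (-0.74 ± 0.07) lower, at a median of 0.17 (adjusted p = 0.0201, and adjusted p = 0.16 with an estimated correlation).

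The antibody changed 34.4% of the features, which may come from the dyes, from an unusual control sample or from the treatment. A dye bias would turn its sign between arrays of opposite labelling, and after turning, the Cy5 and Cy3 sides of the antibody group and of the group with both treatments correlated at 0.887 or more over all features, which argues against it. Single antibody arrays of opposite labelling correlated at 0.691 or more. These values do not cover the IL-13 group, where arrays of opposite labelling correlated at 0.259 and 0.0662. A single unusual control would leave antibody arrays with other controls unrelated, and the lowest correlation between antibody arrays with different control numbers was also 0.691, which argues against it. An effect of the antibody stays as a hypothesis, found and tested on the same data, and the labels do not say whether the control samples received a control antibody.

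Genes known to be raised through the transcription factor ATF4 rose with the antibody, 21 of 24 higher and 0 lower at a median of 0.96, among them SLC38A2 (1.84 ± 0.22), SESN2 (1.42 ± 0.07) and MTHFD2 (1.38 ± 0.09). Of 13 ER chaperone genes 3 were higher and 2 lower at a median of 0.13, and HSPA5 (1.27 ± 0.44) did not pass. The difference of the medians was 0.83, but the ATF4 list was chosen after some of its members had been seen to rise, so this value does not decide between the amino acid stress branch and a general response of the ER. Heat shock from handling would raise heat shock genes, and their median was -0.50 with 5 of 8 lower and 1 higher, which argues against it. What sets off such a response was not tested.

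Other sign patterns and splits of the arrays are too few for a share under 0.05 in 5 comparisons. Turning the sign of 1 of 3 arrays gives 4 patterns, and 1 pattern, the real one, gave 343 calls for IL-13, 7718 for the antibody and 8134 for both treatments, against a highest other count of 0. For both treatments against IL-13, 1 of 10 splits gave 5340 calls, the real one, and the highest other count was 0. For both treatments against anti-EGFR, 2 of 10 splits gave at least 23 calls, and the highest other count was 48. That split follows the dye of the treated RNA and parts all 3 pairs of arrays with the same control number, as the real split does. With the control number as a block the real comparison gave 23 calls.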
